A study of Mus musculus with 3 samples.

How the data were processed

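Mouse hearts in 3 groups, labelled Sham, MI and MI-E, gave 1 single-cell RNA library per group, made from leukocytes sorted on the surface protein CD45 with 10x Genomics 3' chemistry. The labels do not expand MI-E, and they give neither the time after surgery nor the number of hearts pooled. The surgery text attached to the labels is the same for all 3 libraries, Sham included, so what was done to each group is known here only from its name.

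The authors aligned the reads and counted molecules with Cell Ranger 5.0.1 against mm10, per the labels and the file headers. The deposited files hold raw UMI counts, as whole numbers, for 32285 genes in each barcode that Cell Ranger called a cell. The annotation release behind the gene names is not given in the sources used here. Every deposited barcode held at least 500 UMIs. Raw reads were not used here, nor were barcodes outside the called cells, so free RNA in the suspension could only be read from cell types that should lack a gene. Total depth was 41140109 UMIs in Sham, 98814001 in MI and 104562768 in MI-E.

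Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs. Scrublet, as provided in scanpy 1.11.5, scored doublets in each library with an expected rate of 0.8% per 1000 barcodes. Its automatic threshold was used where it marked between 0.5% and 20% of a library, and otherwise the highest scores up to the expected rate were removed. The automatic threshold was used in MI-E, where it marked 291 barcodes, and the expected rate in Sham and MI, where 1032 and 662 were marked. The filters removed 60, 48 and 31 barcodes for low gene number in Sham, MI and MI-E, and 194, 231 and 405 for mitochondrial UMIs.

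Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen per library, gave 30 principal components, 15 neighbours per cell and Leiden clusters at resolution 1. The libraries were not integrated, because library and group are the same thing. This gave 24 clusters. Each was named by the best-scoring of 20 fixed lists of cell type markers with at least 3 markers detected in at least 20% of its cells. A cluster stayed unnamed where its UMI count was low and none of its 10 leading genes was its own marker, or where a second lineage scored at least 0.55. The thresholds for naming were set after the clusters had been seen. Macrophage and monocyte clusters were pooled as monocyte-macrophage cells.

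Within each class, UMIs were summed per library and scaled by the class total to CPM. Log2 ratios are of CPM + 1, and fold values are ratios of CPM. Levels have exact Poisson intervals, ratios the exact interval of a pair of Poisson counts, and shares the exact Clopper-Pearson interval, all at 95%. These intervals cover counting error only. With 1 library per group there is no replicate check on any difference, and no test, p-value or standard error was computed. A gene with 0 UMIs in the lower library is given as a lower bound, against 3 counts over the class, and a share of 0 with the limit that 3 cells would give. Both are one-sided and lie inside the limits of the exact intervals. Monocyte-macrophage cells, neutrophils, T cells, NK cells, B cells and dendritic cells were compared where both libraries held at least 50 cells of the class. Fibroblasts were not among the classes set for comparison.

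There were 26 gene lists, fixed before the data were examined and read in the cell classes they belong to. Lists for interferon response, dissociation stress, proliferation, glycolysis with hypoxia, and oxidative phosphorylation were read in every class. Members with a mean of at least 5 CPM in the class were measured. For each list the median log2 ratio is given with its percentile among 10000 random lists of the same size, matched on expression in 20 bins. Numbers of members at least 1.5-fold higher or lower are given for most lists of monocyte-macrophage cells and, in other classes, where they bear on the median. The percentile describes these libraries and is not a test between groups. Intervals of list medians come from 1000 Poisson resamplings. The symbols Mx1 and Aldoa could not be matched to a single gene and were left out of their lists. Further lists of glucocorticoid targets, cavity macrophage genes and type 17 genes were written after first results had been seen, and the type 17 shares were read with monocyte-macrophage cells as background.

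Genes named in the text follow a rule fixed before the data were examined. In monocyte-macrophage cells these are the 10 highest and 10 lowest log2 ratios for MI over Sham and for MI-E over MI, and 5 and 5 for MI-E over Sham, among genes with at least 50 CPM and UMIs in at least 5% of cells in the higher library. In the other classes they are the 3 highest and 3 lowest with at least 100 CPM. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, predicted gene models, markers of another class, and genes under 10% of their level in another class of the same library were left out. List examples are up to 2 members on each side with at least 20 CPM. All 84 named genes were matched by Ensembl identifier to GENCODE M21 on GRCm38.

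For 16 marker genes, the share of cells with a UMI was counted after thinning cells to 1500 UMIs, in a single random draw, and without thinning. Cells with fewer than 1500 UMIs were left out of the thinned shares, here and for other genes, but not of the unthinned ones. The same share in B cells was read as background, or in T cells in MI, where B cells were too few. The intervals and list percentiles were tested on simulated data with 200 changed genes. The intervals covered 95.4% to 95.6% of unchanged and 93% to 95.5% of changed ratios. The simulated counts were Poisson draws, the model behind the intervals, so coverage near 95% was built in. Spread between cells was not simulated. Changed lists lay at percentile 100, and unchanged lists at 51, 6.35 and 20.6 for MI over Sham, MI-E over MI and MI-E over Sham.

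Alternatives set before the data were examined were edgeR 4.0.16 TMM factors (R 4.3.3), the mean of each cell's own CPM, CPM + 10, other filters on cells and on low genes, doublets kept, Leiden resolution 0.5 and 2, 4000 variable genes with 50 components, each library clustered alone, thinning to 1000 or 3000 UMIs or none, and log2 ratios averaged within clusters holding at least 50 cells of both libraries. Others were added after seeing the data: the expected doublet rate in every library, class sums without clusters 10 and 18, without the monocyte clusters, shares with the low-UMI clusters 2 and 17, and further cell filters for the lists. Calculations used python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9 and umap-learn 0.5.12, and plots matplotlib 3.10.9.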

Results

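Leukocytes from mouse hearts were profiled by droplet single-cell RNA sequencing in 3 groups, with 1 library in each. By their names, Sham is the heart without infarction and MI the heart after myocardial infarction, while MI-E is a name that the labels do not expand. The series asks about macrophages that reside only for a time in the infarcted heart and about remodelling of the ventricle. The Sham library held 11357 barcodes with a median of 2727 UMIs, MI 9095 with a median of 9604, and MI-E 12707 with a median of 7287. After removal of poor cells and predicted doublets, 10079 cells remained in Sham, 8169 in MI and 11989 in MI-E. Each difference below is a difference between 2 libraries and has no replicate check.

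Monocytes and macrophages made up 38.2% of Sham cells (95% interval 37.3 to 39.2), 78.1% of MI cells (77.2 to 79.0) and 55.3% of MI-E cells (54.4 to 56.2). Neutrophils, the first granulocytes to enter injured tissue, were 4.20% of Sham (3.81 to 4.61) and 4.41% of MI (3.97 to 4.87) but 25.1% of MI-E (24.3 to 25.9). B cells were 29.4% of Sham, 0.575% of MI and 2.64% of MI-E. T cells were 7.08%, 0.894% and 2.25%, and NK cells 3.01%, 0.428% and 0.667%, in the same order. Dendritic cells were 1.32%, 3.71% and 4.40%. Innate lymphoid cells of type 2 were 0.308% of Sham (0.209 to 0.436) and 0.00834% of MI-E, and 0 of 8169 cells in MI, which allows a share of up to 0.0367%. Fibroblasts, which the CD45 sort should exclude, were 0.506%, 0.808% and 1.18%.

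**Figure D1:**
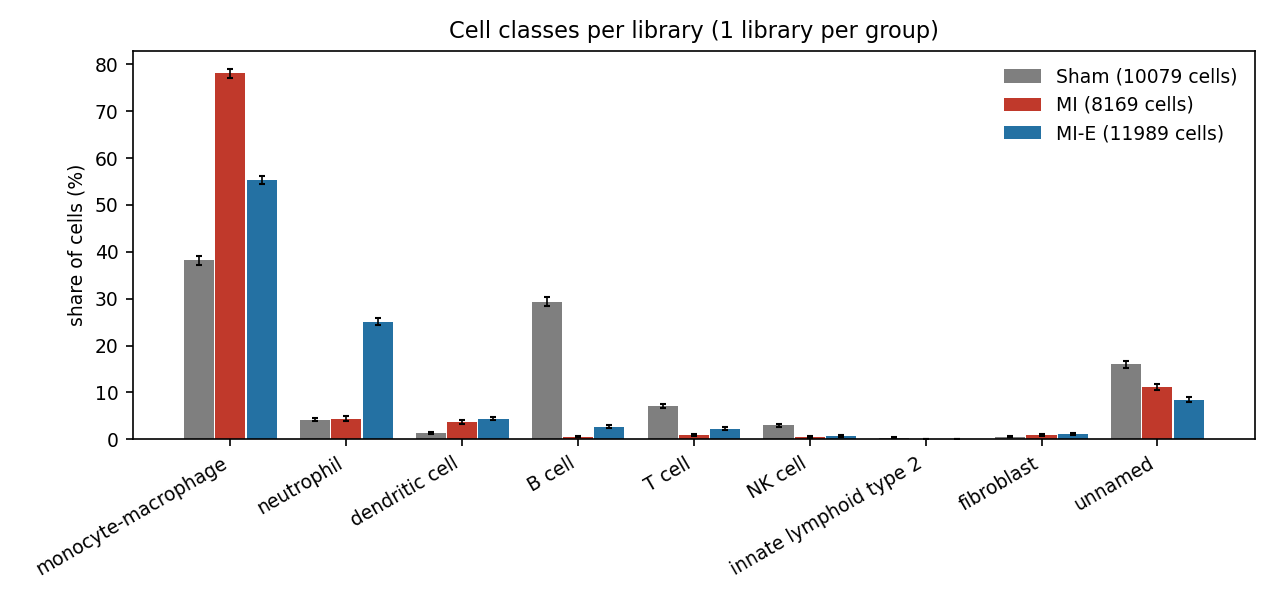
Share of filtered cells in each cell class (percent) in the Sham, MI and MI-E libraries, with exact 95% intervals for counting error. Monocyte-macrophage cells make up 78.1% of MI and neutrophils 25.1% of MI-E.

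As ratios of shares, monocyte-macrophage cells were 2.04-fold higher in MI than in Sham (1.96 to 2.13) and 1.41-fold lower in MI-E than in MI (1.36 to 1.46). Shares in a library are parts of the same total, so the higher neutrophil share of MI-E by itself lowers its other shares. The neutrophil share was 5.69-fold higher in MI-E than in MI (5.10 to 6.37) and 5.98-fold higher than in Sham, while MI and Sham did not differ beyond counting error (1.05, 0.910 to 1.21). The B cell share was 51.1-fold lower in MI than in Sham (38.3 to 69.7), and 11.1-fold lower in MI-E. The T cell share was 7.93-fold lower in MI than in Sham (6.22 to 10.2) and that of NK cells 7.02-fold lower (4.94 to 10.3). Against MI, the MI-E shares of B, T and NK cells were 4.60-fold, 2.52-fold and 1.56-fold higher. Dendritic cells were 2.81-fold higher in MI than in Sham (2.29 to 3.47). With each library clustered alone, the ratio of T cell shares of MI to Sham was 0.191 in place of 0.126.

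The monocyte-macrophage share rests on clusters 10 and 18. Their 10 leading genes against all other cells held 1 gene of the list for type 2 innate lymphoid cells (Areg or Rnf128) and 0 macrophage markers, although 11 and 12 macrophage markers were detected in them. Macrophage clusters 3, 4, 14, 16 and 23 also held 0 there. Against other lineages, the leading genes of cluster 18 held 2 macrophage markers and 0 others, and those of cluster 10 held 1 and 1. With these clusters taken out of the class but their cells kept in the total, the class made up 38.2% of Sham, 43.9% of MI and 32.0% of MI-E. The ratio of MI to Sham was then 1.15 and that of MI-E to Sham turned from 1.45 to 0.839. The clusters held 3 and 2 Sham cells, 1120 and 1670 MI cells, and 1845 and 952 MI-E cells. Counting them as other cells could therefore lower little but the MI and MI-E shares.

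Clusters left without a name held 1610 of 10079 Sham cells, 11.1% of MI cells and 8.42% of MI-E cells. The largest in Sham was cluster 2, low-UMI cells with 10.9% of the library, which scored highest as macrophage, as did low-UMI cluster 17. With both added, monocyte-macrophage cells made up 49.5% of Sham, 84.3% of MI and 58.7% of MI-E, and the ratio of MI to Sham was 1.70 in place of 2.04. Markers of other cell types were summed in each class. Red blood cell markers came to 11053 CPM in Sham NK cells, far above the other Sham classes (37.1 CPM in dendritic cells to 122 CPM in neutrophils) and the NK cells of MI-E (18.4 CPM), so this value is not a measure of free RNA. Neutrophil markers came to 391 CPM in Sham monocyte-macrophage cells, 192 CPM in MI and 390 CPM in MI-E, to 597, 36.0 and 391 CPM in T cells, and to 145, 305 and 701 CPM in dendritic cells. In NK cells they came to 755 CPM in Sham and 1344 CPM in MI-E, and in B cells to 54.1 and 272 CPM. Most of each dendritic cell sum was a gene of this list, Il1r2, at 107, 281 and 433 CPM. The dendritic cell sums are therefore not a measure of free RNA. In T cells Il1r2 stood at 13.1, 24.8 and 51.2 CPM. Cardiomyocyte markers summed to 103 CPM in Sham monocyte-macrophage cells, 19.6 CPM in MI and 33.7 CPM in MI-E, and endothelial markers to 85.8, 207 and 122 CPM. B cell markers summed to 209, 18.8 and 31.5 CPM in the same cells. The endothelial list holds Fabp4, which is also in the nonclassical monocyte list, so the endothelial sums in monocyte-macrophage cells need not measure free RNA. In the order Sham, MI and MI-E, endothelial sums were 29.6, 38.3 and 68.0 CPM in T cells. They were 16.9, 24.2 and 55.5 CPM in dendritic cells and 29.5, 57.4 and 56.1 CPM in neutrophils.

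The comparison of MI with Sham asks how macrophages of the infarcted heart differed from those of the heart without infarction. Most genes of the lipid-handling Trem2 list were higher in MI. Spp1, which encodes osteopontin, stood at 6951 CPM in MI and 32.8 CPM in Sham, a ratio of 212 (197 to 228). Arg1, the arginase of repair-type macrophages, stood at 513 CPM in MI and rested on 3 UMIs of 1 cell in Sham, a ratio of 3662 (1253 to 17759) whose interval leaves out that they come from 1 cell. Genes of resident macrophages and of antigen presentation were lower in MI: Timd4, a receptor for dying cells found on long-lived resident macrophages, was 37.2-fold lower (31.7 to 44.0). Retnla, a gene of the repair, matrix and growth factor list, was 791-fold lower (625 to 1017). Class medians were 5042.5 UMIs per cell in Sham and 10209 in MI, over 3852 and 6378 cells.

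Among the 10 genes with the highest ratios were also the acute-phase gene Saa3 (204 CPM in MI, on 15 UMIs in Sham, 291-fold), Gpnmb (138-fold), the fatty acid binding protein gene Fabp5 (3190 against 44.0 CPM, 72.5-fold), Pdpn (69.4-fold) and Syngr1 (64.0-fold). Mmp14, a membrane-bound matrix protease, was 58.8-fold higher, Ly6a 45.0-fold and the angiogenic factor Vegfa 20.2-fold. On the lower side, the inducible heat shock genes Hspa1b and Hspa1a stood at 2397 and 3716 CPM in Sham and were 62.0-fold and 41.7-fold lower in MI. Serpinf1 was 42.5-fold lower, Fxyd2 37.6-fold, and Hpgd, which degrades prostaglandins, 30.6-fold. Lilra5 and Tcim were each 29.8-fold lower and the lectin gene Mgl2 21.7-fold. Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050, Arg1 (ENSMUSG00000019987) on chromosome 10 from 24915221 to 24927484, and Timd4 (ENSMUSG00000055546) on chromosome 11 from 46810800 to 46844332 of GRCm38.

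The resident cardiac macrophage list had a median log2 ratio of -2.47 (-2.51 to -2.42), at percentile 0 of random lists, with 16 of 17 measured members at least 1.5-fold lower and Ninj1 between. Cd209f was 79.5-fold lower. All 6 measured MHC class II genes were lower, with a median of -2.90 (-2.91 to -2.89, percentile 0). Cd74, the invariant chain, stood at 12805 CPM in Sham and 1488 CPM in MI and H2-Eb1 was 9.27-fold lower. B cells express these genes, and B cell markers in the same cells were also lower, at 209 CPM in Sham and 18.8 CPM in MI. The lipid-handling Trem2 list had a median of 1.59 (1.57 to 1.61, percentile 100), with 11 of 16 members higher. Its single lower member was Apoe, an abundant lipid carrier, at 24768 CPM in Sham and 8413 CPM in MI. The classical monocyte list had a median of 1.66 (percentile 100), with 13 of 14 members higher and Thbs1 9.04-fold higher. The nonclassical monocyte list had a median of -0.87 (percentile 0.155), with 8 of 11 members lower, among them Stap1 (2.92-fold), and Fabp4 3.05-fold higher.

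The repair, matrix and growth factor list went both ways, with 13 of 22 members higher, 7 lower and a median of 1.21 (percentile 100). Arg1 and Mmp14 were among the higher members, and Retnla (791-fold) and the collagenase gene Mmp13 (8.17-fold) among the lower. Inflammatory cytokine and chemokine genes had a median of -0.000127 (percentile 10.2), with 3 of 15 higher and 4 lower. Ptgs2, which makes prostaglandins, was 11.5-fold and Cxcl3 5.02-fold higher, while Ccl3 was 5.90-fold and Ccl4 3.22-fold lower. Efferocytosis and scavenger receptor genes had a median of -0.26 (percentile 2.03), with 5 of 16 higher, such as the receptor gene Lrp1 (3.60-fold), and 6 lower, such as the complement gene C1qc (2.60-fold). Type I interferon response genes had a median of 1.21 (percentile 100), with 10 of 17 higher and 2 lower. The regulator Irf7 was 5.40-fold higher and the chemokine Cxcl10 1.76-fold lower.

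Metabolic lists were mostly higher in MI. Glycolysis and hypoxia genes had a median of 1.48 (percentile 100), with 16 of 20 members higher, Hilpda 6.55-fold, and 2 lower, Pfkfb3 2.76-fold. Oxidative phosphorylation genes had a median of 0.80 (percentile 99.4), with 15 of 19 higher, Cox5a 2.70-fold, while the median share of mitochondrial UMIs was 2.63% in Sham, 1.21% in MI and 1.71% in MI-E. Lysosome genes had a median of 0.76 (percentile 99.4), with 10 of 18 higher, among them the protease gene Ctsd (11.2-fold), and 0 lower. Cholesterol and LXR target genes had a median of 0.69 (percentile 99.4), with 7 of 12 higher, Nr1h3 6.33-fold, and 3 lower. Iron handling genes had a median of -0.53 (percentile 0.510), with 5 of 11 lower, the haemoglobin scavenger Cd163 10.2-fold and Trf 7.43-fold, and the ferritin gene Fth1 2.19-fold higher. Proliferation genes had a median of 1.58 (percentile 100), with 18 of 20 higher, Pclaf 8.75-fold. Dissociation stress genes had a median of -1.72 (percentile 0), with 18 of 19 lower, the heat shock genes foremost.

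**Figure D2:**
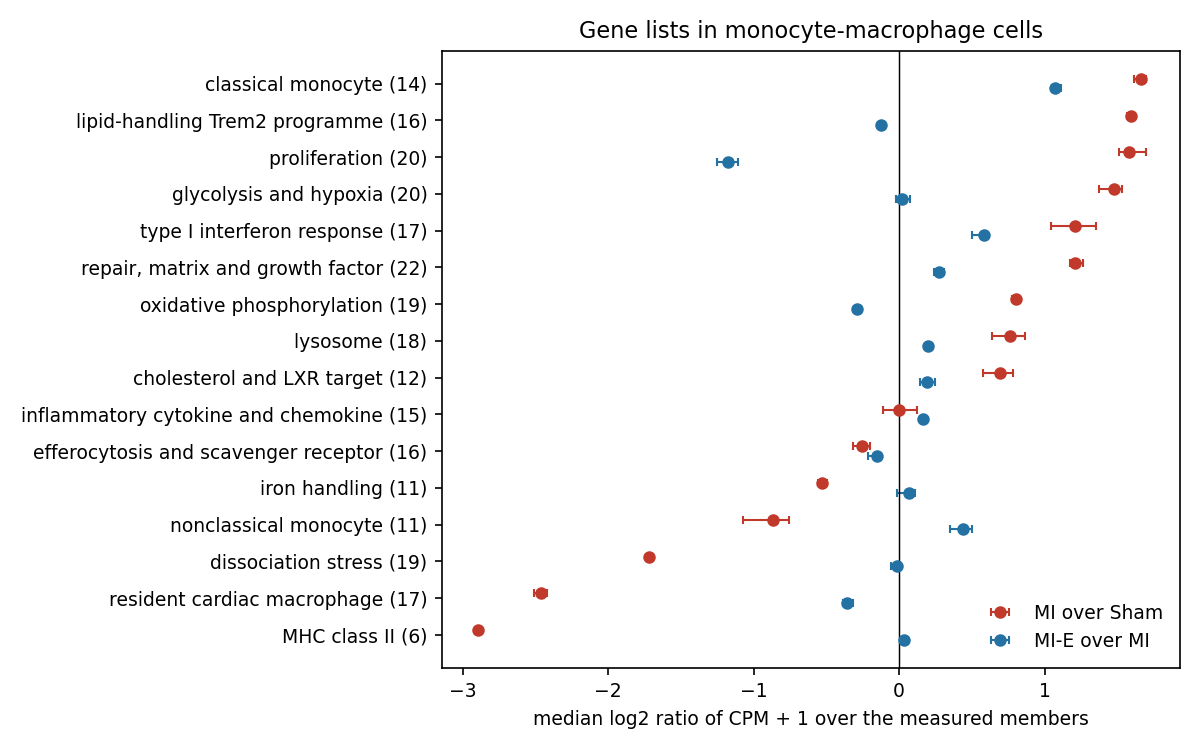
Median log2 ratio of each gene list in monocyte-macrophage cells for MI over Sham and MI-E over MI. The MHC class II median is -2.90 for MI over Sham and 0.04 for MI-E over MI.

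Sham and MI drew their cells from different clusters: 48.8% and 36.3% of the Sham class lay in clusters 3 and 4, and 26.2%, 21.5% and 17.6% of the MI class in clusters 18, 8 and 10. Within clusters 3 and 9, the only clusters with at least 50 cells of both, the medians were -0.46 for resident, -1.54 for MHC class II, 1.04 for classical monocyte, 0.92 for Trem2 and -0.61 for stress genes, and the inflammatory median was 1.14. The nonclassical monocyte and efferocytosis medians turned to 0.16 and 1.09. Named genes kept their direction there, with log2 ratios of 4.93 for Spp1, 6.22 for Arg1, -0.99 for Timd4 and -3.03 for Retnla. The MHC class II median was -2.27 with no filter on low genes, and the proliferation median 2.22 without clusters 10 and 18 and 0.96 with CPM + 10. The median over all genes was 0.13, and 0.31 with TMM factors.

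Shares of cells with a UMI, after thinning to 1500 UMIs, followed these levels. Retnla, at 740 CPM in Sham, was carried by few cells: it was seen in 6.14% of Sham and 0.0792% of MI cells (9.24% and 0.267% unthinned), against 1.03% of Sham B cells and 0 of 72 MI T cells. Timd4 was seen in 9.49% of Sham and 0.285% of MI cells (26.3% and 1.69% unthinned), against 0.0732% of Sham B cells and 0 of 72 MI T cells, which allows up to 4.17%. Lyve1, a hyaluronan receptor, was seen in 23.7% and 2.33% (40.8% and 5.49% unthinned), against 0.330% of Sham B cells and 0 of the same T cells. Trem2, a lipid-sensing receptor, was seen in 23.7% of Sham and 53.5% of MI cells (51.0% and 88.4% unthinned), against 0.439% and 2.78%. Spp1 was seen in 2.42% and 78.9% (4.52% and 94.2% unthinned), against 0.293% and 20.8%. Arg1 was seen in 0.0266% of Sham and 32.2% of MI cells (0.0260% and 58.9% unthinned), against 0 of 2731 Sham B cells, which allows up to 0.110%, and 1.39% of MI T cells, so that the Sham share is read as background. Ccr2, a receptor of recruited monocytes, was seen in 4.41% and 19.2% (9.61% and 55.2% unthinned), against 0.0366% and 5.56%, the latter in T cells, which can express it. Median depth was 2299 UMIs in the Sham B cells and 3893 in the MI T cells.

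**Figure D3:**
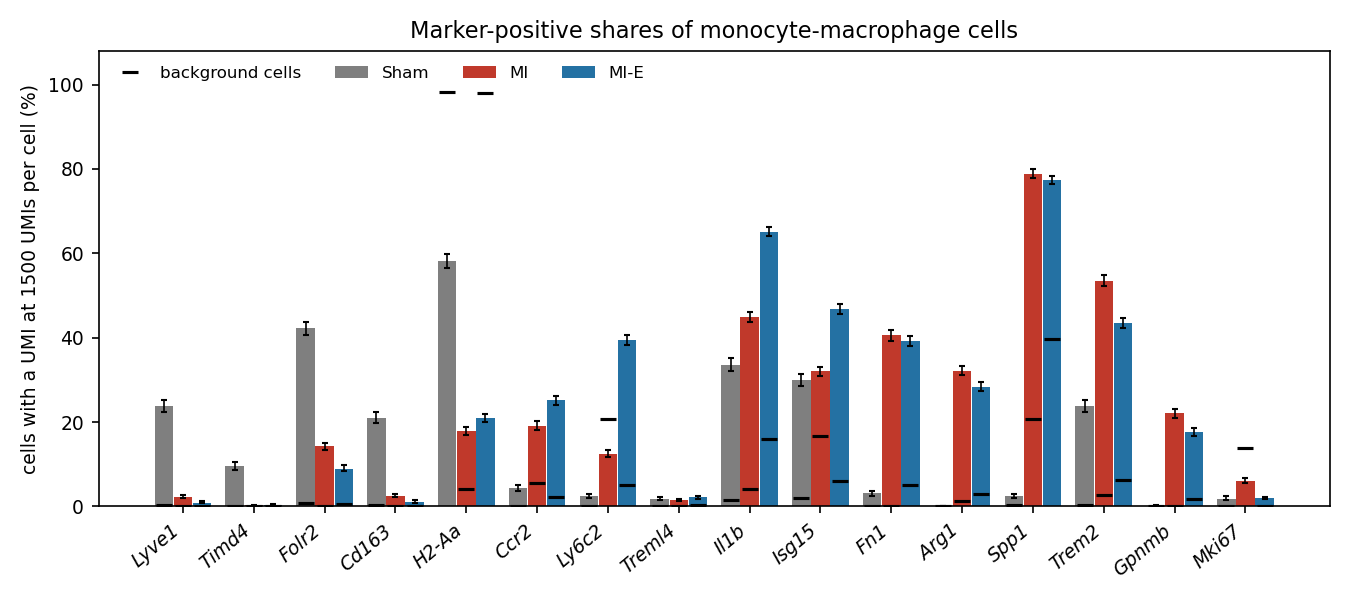
Share of monocyte-macrophage cells (percent) with at least 1 UMI of 16 marker genes after thinning to 1500 UMIs, by library, with exact 95% intervals and the share in the background cell type. Spp1 is seen in 2.42% of Sham cells and 78.9% of MI cells.

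In the comparison of MI-E with MI, monocyte-macrophage cells of MI-E held more transcripts of blood-type monocytes and of the interferon response, and fewer of cell division. Ly6c2, a surface marker of classical monocytes, stood at 568 CPM in MI-E and 124 CPM in MI, 4.57-fold higher (4.47 to 4.68). The cell cycle gene Pclaf stood at 21.8 CPM in MI-E and 87.0 CPM in MI, and Fkbp5, a co-chaperone of steroid receptors, stood at 11.8 CPM in MI-E and 58.7 CPM in MI, 4.98-fold lower (4.63 to 5.36). The Trem2 and MHC class II lists differed little. The resident list had a lower median, but only 6 of 17 members were at least 1.5-fold lower and its sign turned within clusters. Class medians were 9681 UMIs per cell in MI-E and 10209 in MI, over 6635 and 6378 cells.

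The other genes with the highest ratios were Chil3, a chitinase-like gene of monocytes (1044 against 306 CPM, 3.42-fold), Ifitm6 (3.27-fold), Plac8 (1373 against 512 CPM, 2.68-fold), Ms4a4c (2.59-fold) and coagulation factor X, F10 (2.37-fold). The interferon-induced genes Irf7, Oas3, Ifi205 and Zbp1 were 2.51-fold, 2.47-fold, 2.38-fold and 2.36-fold higher. Those with the lowest ratios were mainly genes of DNA replication and mitosis. The histone gene Hist1h2ae was 5.48-fold lower, Birc5 3.77-fold, Ube2c 3.65-fold, Cks1b 3.24-fold, Dut 3.22-fold and Stmn1 2.94-fold. Mki67, the gene of the Ki-67 protein of cycling cells, was 2.93-fold and the topoisomerase gene Top2a 2.82-fold lower. Ly6c2 (ENSMUSG00000022584) lies on chromosome 15 from 75108158 to 75111970 and Fkbp5 (ENSMUSG00000024222) on chromosome 17 from 28399094 to 28517527.

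**Figure D4:**
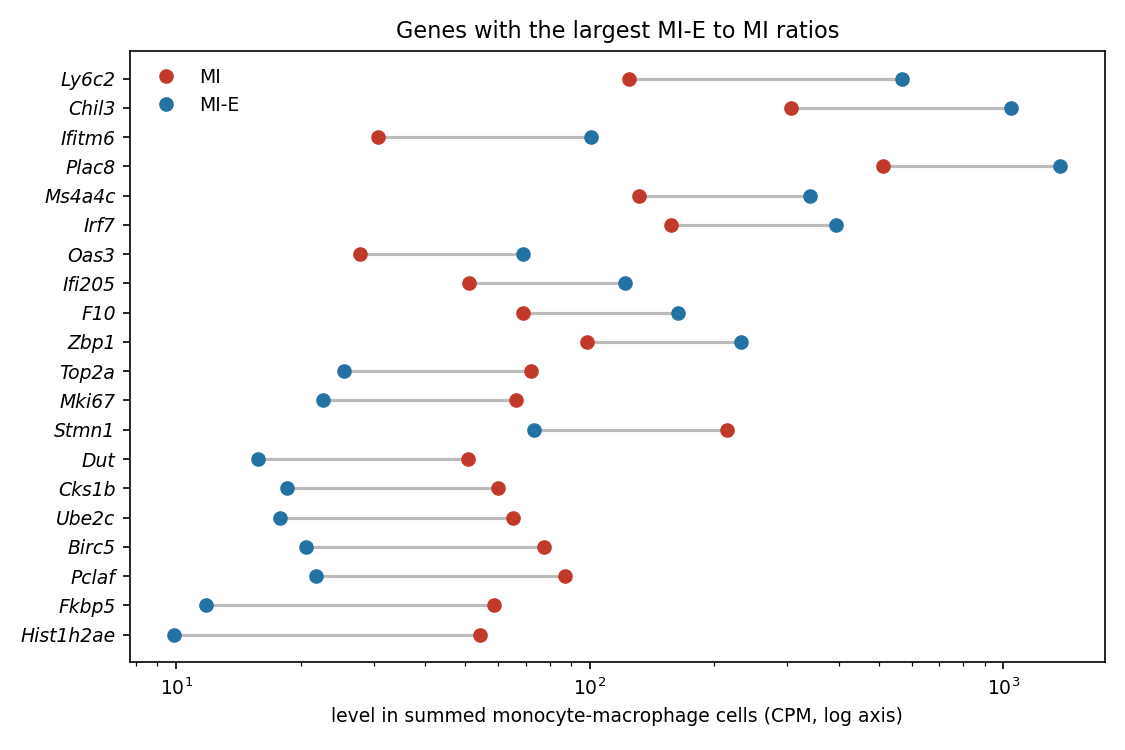
Levels in CPM (log axis) of the named genes in monocyte-macrophage cells of MI and MI-E. Ly6c2 stands at 124 CPM in MI and 568 CPM in MI-E, and Fkbp5 at 58.7 and 11.8 CPM.

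The classical monocyte list had a median log2 ratio of 1.07 (1.05 to 1.11, percentile 100), with 10 of 14 members higher and 0 lower. The nonclassical monocyte list had a median of 0.44 (percentile 100), with 3 of 11 higher, the integrin gene Itgal 2.96-fold, and Fabp4 1.95-fold lower. Type I interferon response genes had a median of 0.58 (0.50 to 0.60, percentile 100), with 8 of 17 higher and 0 lower. Proliferation genes had a median of -1.18 (-1.25 to -1.11, percentile 0), with 17 of 20 lower. The resident list had a median of -0.36 (percentile 0), with 6 of 17 lower, among them Ltc4s (2.44-fold) and the growth factor Igf1 (1.79-fold), and Ccl24 1.69-fold higher. All 6 MHC class II genes lay between (median 0.04, percentile 59.2), with Cd74 1.09-fold lower. So did all 16 Trem2 genes (median -0.12, percentile 14.7), with Syngr1 1.36-fold lower and Lgals3 1.18-fold higher.

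Inflammatory genes had a median of 0.17 (percentile 92), with 4 of 15 higher, Il1b 1.76-fold and Il18 1.68-fold. Repair genes had a median of 0.27 (percentile 99.8), with 3 of 22 higher, such as Thbs1 (1.88-fold), and 2 lower, such as the elastase gene Mmp12 (1.92-fold). Efferocytosis genes had a median of -0.15 (percentile 3.62), with the receptor kinase gene Mertk 2.15-fold lower and 15 of 16 between. Cholesterol and LXR genes had a median of 0.19 (percentile 95.6), with 11 of 12 between, among them Nr1h3 (1.45-fold higher). All 18 lysosome genes lay between (median 0.20, percentile 97), Ctsd 1.06-fold lower. Iron genes had a median of 0.07 (percentile 65.2), with Cd163 1.79-fold lower and 10 of 11 between. All 19 stress genes lay between (median -0.02, percentile 47.6), Hspa1a 1.37-fold higher. Glycolysis and hypoxia genes had a median of 0.02 (percentile 41.2), with Slc16a3 1.87-fold higher and Bnip3 1.72-fold lower. Oxidative phosphorylation genes had a median of -0.29 (percentile 0.190), with Ndufa1 1.60-fold lower and 18 of 19 between.

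Ly6c2 was seen in 12.5% of MI and 39.3% of MI-E cells after thinning (31.4% and 68.1% unthinned), against 20.8% of MI T cells and 5.02% of MI-E B cells. T cells can express Ly6c2, so the MI value is not a measure of free RNA. Mki67 was seen in 6.13% and 1.98% (20.5% and 9.24% unthinned), against 13.9% of MI T cells, which themselves can divide, and 0 of 299 MI-E B cells, which allows up to 1.00%. Il1b, the interleukin 1 beta gene, was seen in 45.0% and 65.2% (66.7% and 89.3% unthinned), against 4.17% and 16.1%. The interferon-induced Isg15 was seen in 32.0% and 46.8% (70.0% and 86.5% unthinned), against 16.7% of MI T cells, which themselves held more interferon transcripts than those of Sham, and 6.02%. Spp1 was seen in 78.9% and 77.3% (94.2% and 95.9% unthinned), against 20.8% and 39.8%. Gpnmb was seen in 22.1% and 17.6% (46.1% and 42.5% unthinned), against 0 of 72 MI T cells and 1.67% of MI-E B cells. Median depth was 2166 UMIs in the MI-E B cells.

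Neutrophil markers summed to 192 CPM in MI and 390 CPM in MI-E monocyte-macrophage cells. MI-E cells lay mostly in clusters 10, 9 and 7, which held 27.8%, 19.1% and 16.7% of the class. Within the 7 clusters with at least 50 cells of both libraries the proliferation median was -0.21, with 1 member lower in place of 17, and Pclaf and Fkbp5 had log2 ratios of -0.92 and -2.05. The resident, nonclassical, Trem2 and inflammatory medians turned to 0.04, -0.01, 0.11 and -0.03 there. The inflammatory median also turned to -0.17 without clusters 10 and 18, and the MHC class II median to -3.86e-05 with doublets kept.

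MI-E against Sham, the third comparison, shares its libraries with the others and adds no independent evidence. In monocyte-macrophage cells of MI-E over Sham, Arg1, again on 3 UMIs of 1 Sham cell, had a ratio of 4491 (1537 to 21778), and Saa3 was 309-fold, Spp1 200-fold (186 to 216), Gpnmb 135-fold and Ly6a 95.3-fold higher. Retnla was 2012-fold lower (1382 to 3054), Fxyd2 82.9-fold, Hpgd 62.5-fold, Mgl2 50.2-fold and Hspa1b 48.9-fold.

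The classical monocyte list had a median log2 ratio of 3.07 (percentile 100), with 14 of 14 members higher, Ms4a4c 18.4-fold. The resident median was -2.83 (percentile 0; 16 of 17 lower, Lyve1 28.0-fold) and the MHC class II median -2.86 (percentile 0; 6 of 6 lower). Interferon genes had a median of 1.99 (percentile 100), with 11 of 17 higher, Irf7 13.5-fold. Repair genes had a median of 1.82 (percentile 100; 12 of 22 higher, 7 lower) and Trem2 genes 1.37 (percentile 100; 11 of 16 higher). Nonclassical monocyte genes had a median of -0.59 (percentile 1.12; 6 of 11 lower), inflammatory genes 0.10 (percentile 30) with Ptgs2 17.3-fold higher and Ccl4 4.42-fold lower, and efferocytosis genes -0.26 (percentile 1.14) with Msr1 3.55-fold higher and C1qc 3.58-fold lower. Cholesterol genes had a median of 0.86 (percentile 99.8), lysosome genes 0.86 (percentile 99.9), iron genes -0.29 (percentile 2.54), glycolysis and hypoxia genes 1.41 (percentile 100) and oxidative phosphorylation genes 0.63 (percentile 97.2). Proliferation genes had a median of 0.47 (percentile 96.5), with 8 of 20 higher, and stress genes -1.92 (percentile 0), with 17 of 19 lower.

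Only 3 clusters held at least 50 cells of both MI-E and Sham. Within them the medians were -0.38 for resident, 1.36 for classical monocyte, -0.04 for MHC class II, 1.23 for inflammatory, 0.82 for repair and -0.22 for stress genes, and those of efferocytosis and iron genes turned to 1.03 and 0.09. The inflammatory median turned to -0.44 without clusters 10 and 18 and the nonclassical median to 0.09 at a mean of at least 20 CPM. The MHC class II median was -2.22 with no filter on low genes and the interferon median 1.13 with CPM + 10.

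Neutrophils of MI and of MI-E held more transcripts of the activation and ageing list and of the interferon response than those of Sham. B cell markers summed to 639 CPM in Sham neutrophils, 44.2 CPM in MI and 38.0 CPM in MI-E, and red blood cell markers to 122, 20.3 and 26.7 CPM. In MI over Sham, Il1a, an early inflammatory cytokine, stood at 408 against 11.1 CPM (36.9-fold, 19.2 to 81.3), Ifit3 was 36.0-fold higher (13.8 to 134), and Il23a, on 2 UMIs in Sham, had a ratio of 59.9 (16.2 to 500). Mgst1, Sh2d3c and Impact were 9.25-fold, 6.66-fold and 5.74-fold lower. The activation and ageing list had a median of 2.70 (percentile 100), with 14 of 16 members higher, Icam1 13.2-fold. Interferon genes had a median of 1.97 (percentile 100; 13 of 16 higher), or 1.71 with Usp18, at 0 UMIs in Sham, set to its bound, and 1.12 with CPM + 10. The trafficking list had a median of -0.31 (percentile 8.68), with the alarmin genes S100a8 and S100a9 3.19-fold and 3.38-fold lower, and the early granule list -0.02 (percentile 21.1), with Lcn2 3.75-fold lower and Chil3 3.77-fold higher. Stress, glycolysis and oxidative phosphorylation medians were 0.48, 0.44 and 0.65 (percentiles 96.8, 84.5 and 97.7). Only 6 of 20 proliferation genes were measured (median 0.96, percentile 92.9, and 0.33 at a mean of at least 20 CPM).

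Between MI-E and MI neutrophils differed less. Stfa2l1, a cystatin-like gene, was 2.57-fold, Zbp1 2.28-fold and Oas3 2.16-fold higher in MI-E than in MI, and Fn1, Tsc22d3 and Klhl6 were 3.50-fold, 3.16-fold and 2.39-fold lower. The Fn1 ratio rests on 103 UMIs in 25 MI cells. Thinning kept 248 of 360 MI and 2585 of 3008 MI-E neutrophils. After thinning Fn1 was seen in 2.82% of MI and 5.45% of MI-E neutrophils (6.94% and 8.71% unthinned), against 2.78% of MI T cells and 4.35% of MI-E B cells (12.3% and 5.99% unthinned). The MI background is 2 of 72 cells in this thinning and 0 in that of the 16 marker genes, which allows up to 4.17%, so Fn1 in neutrophils cannot be told from background. Median depth was 1764.5 and 2107.5 UMIs in these neutrophils. Early granule genes had a median of 0.58 (percentile 100), with 5 of 11 higher, among them Ngp, on 2 UMIs in MI, with a ratio of 24.4 (6.73 to 202), interferon genes 0.58 (percentile 100; 8 of 16 higher), trafficking genes 0.30 (percentile 99.1), Fpr2 2.00-fold, and activation genes 0.17 (percentile 95.7). Oxidative phosphorylation genes had a median of -0.35 (percentile 0.13), Ndufa4 2.12-fold lower. Stress, proliferation and glycolysis medians were 0.05, -0.02 and -0.10 (percentiles 76, 61 and 25.2), and the last turned to 0.04 with TMM factors.

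In MI-E over Sham, Ifit3 was 55.4-fold (21.6 to 204) and Il1a 47.4-fold higher, and Ifit3b, with 879 UMIs against 0, was at least 29.2-fold higher (lower limit of the exact interval 23.7). Impact, Cyth1 and Il15 were 6.06-fold, 5.68-fold and 5.44-fold lower. Activation genes had a median of 2.68 (percentile 100), interferon genes 2.35 (percentile 100), with Usp18 at least 7.08-fold higher, early granule genes 0.25 (percentile 54.8; 4 of 11 higher and 4 lower), trafficking genes -0.27 (percentile 10.4), stress genes 0.39 (percentile 95.1), proliferation genes 0.80 (percentile 90.8), glycolysis genes 0.39 (percentile 83.5) and oxidative phosphorylation genes 0.23 (percentile 64.9). Of the Sham neutrophils 402 of 423 lay in cluster 5, while 93.6% of those in MI and 98.3% in MI-E lay in cluster 22. Within cluster 5, the single cluster with 50 cells of both MI-E and Sham, the activation, interferon and early granule medians were 0.93, 0.98 and 1.36, and those of trafficking, stress, proliferation and oxidative phosphorylation turned to 0.23, -0.42, -0.58 and -0.32. The interferon median was 1.60 with CPM + 10, and the proliferation median -0.06 at a mean of at least 20 CPM. The median over all neutrophil genes for MI over Sham was 0.38, and 0.12 with TMM factors.

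The 73 T cells of MI carried many transcripts of cell division. Pclaf and Hist1h1b stood at 509 and 554 CPM in MI, 194-fold (92.6 to 488) and 185-fold higher than in the 714 T cells of Sham, and Nusap1, on 3 UMIs in Sham, had a ratio of 156 (51.5 to 774). Rflnb, Tubb2a and Dusp10 were 8.40-fold, 4.44-fold and 4.32-fold lower. In MI over Sham the proliferation median was 4.09 (percentile 100; 18 of 20 higher), and 3.34 and 2.73 with the mean of per-cell CPM and with CPM + 10. Naive T cell genes had a median of -1.19 (percentile 0; 8 of 10 lower, Klf2 2.74-fold), or -0.59 with per-cell CPM. Effector genes had a median of 1.34 (percentile 100; Gzmb 8.02-fold higher), regulatory T cell genes 1.93 (percentile 100; Ctla4 11.3-fold), checkpoint receptor genes 2.07 (percentile 100; Pdcd1 8.88-fold) and interferon genes 1.60 (percentile 100; 15 of 15 higher), where the last pair were 1.07 and 1.01 with CPM + 10. Glycolysis and oxidative phosphorylation medians were 1.10 and 0.92 (percentiles 100 and 99.7) and the stress median -0.48 (percentile 0.01), Hspa1b 8.82-fold lower.

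In T cells of MI-E over MI, Il22 and Cxcl1, a cytokine and a neutrophil-attracting chemokine, were each 5.72-fold higher (2.93 to 12.8), and Smpdl3a was 3.68-fold higher. The histone genes Hist1h2ae, Hist1h1e and Hist1h2ap were 8.71-fold, 7.79-fold and 7.49-fold lower. The proliferation median was -1.83 (percentile 0; 18 of 20 lower) and that of checkpoint receptors -1.08 (percentile 0.150; Pdcd1 3.14-fold lower). Medians were 0.30 for naive (percentile 97.4), 0.19 for effector (-0.87 to 0.24, percentile 90.8; 3 of 15 higher and 7 lower, so without a common direction), 0.34 for regulatory (-0.10 to 0.65, percentile 94.2; 4 of 10 higher and 3 lower), 0.16 for interferon (percentile 71.6), 0.28 for stress (percentile 99), -0.11 for glycolysis (percentile 25.1) and -0.54 for oxidative phosphorylation genes (percentile 0.01), where the median share of mitochondrial UMIs was 2.84% in MI-E, 2.12% in Sham and lower than both in MI. The naive median turned to -0.24 with per-cell CPM, and the regulatory median was -0.31 at a mean of at least 20 CPM.

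In T cells of MI-E over Sham, Il17a was 48.0-fold (22.7 to 121) and Cxcl1 44.2-fold higher, Il22, with 138 UMIs against 0, at least 103-fold higher (exact lower limit 82.7), and Dusp10, Tubb2a and Cct6a were 6.29-fold, 5.95-fold and 3.80-fold lower. Cxcl1 stood at 2.62, 20.3 and 116 CPM in T cells of Sham, MI and MI-E, against 458, 688 and 711 CPM in monocyte-macrophage cells, and was also higher in MI-E than in Sham B cells, at 60.1 and 4.09 CPM. Medians were -0.81 for naive (percentile 0), 0.65 for effector (percentile 98.2), 1.91 for regulatory (percentile 100), 1.25 for checkpoint (percentile 99.2), 2.07 for interferon (percentile 100), 1.99 for proliferation (percentile 100), 0.86 for glycolysis (percentile 99.9), 0.48 for oxidative phosphorylation (percentile 94.7) and -0.08 for stress genes (percentile 1.69). The effector median was 1.39 at a mean of at least 20 CPM, the checkpoint median 0.64 with CPM + 10, and the proliferation median 1.30 with per-cell CPM and 1.15 with CPM + 10. TMM factors moved the median over all T cell genes from 0.26 to -0.11 for MI over Sham and from 0.29 to -0.06 for MI-E over Sham.

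NK and B cells were too few in MI and were compared between MI-E and Sham. In NK cells the cytotoxic list had a median of -0.56 (percentile 0.03), with 6 of 12 members lower, among them Ccl4 (3.09-fold), and interferon genes had a median of 1.14 (percentile 100; Oas3 at least 6.83-fold higher), or 1.84 with doublets kept. Hist1h1b was 13.3-fold higher. Thbs1 and Spp1 had ratios of 175 (30.5 to 7014), on 1 UMI in Sham, and 25.7, yet both stood far higher in MI-E monocyte-macrophage cells, at 1855 and 6567 CPM against 202 and 684 CPM here, and Spp1 was also seen in MI-E B cells. Bambi, Ikzf3 and Ndfip2 were 4.30-fold, 3.38-fold and 3.33-fold lower. Proliferation, glycolysis, oxidative phosphorylation and stress medians were 0.99, 0.40, 0.07 and -0.26 (percentiles 100, 99.8, 69.9 and 2.29).

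In B cells the interferon gene Irf7 stood at 124 CPM in MI-E and 24.8 CPM in Sham, and Ifi27l2a was 3.27-fold higher. Ppp1r15a, Plaur and Hes1 were 3.89-fold, 3.23-fold and 3.05-fold lower. The interferon list had a median of 1.07 (percentile 100; 7 of 10 higher), or 1.93 at a mean of at least 20 CPM. The B cell activation list had a median of 0.28, against a median of -0.02 in random lists, with 4 of 10 higher, Egr1 3.84-fold, and 3 lower, Cd86 1.87-fold. Glycolysis, proliferation, oxidative phosphorylation and stress medians were 0.48, 0.21, -0.01 and -0.25 (percentiles 100, 92.7, 55.3 and 2.15), and of the 10 proliferation genes 2 were higher and 2 lower.

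Dendritic cells of MI and of MI-E held more interferon-induced transcripts than those of Sham. In MI over Sham, Ly6a stood at 437 against 10.6 CPM (41.3-fold, 22.4 to 86.4), and Ifitm1 and Timp1 were 18.7-fold and 17.6-fold higher. Cd81, Mt2 and Trf were 16.6-fold, 10.7-fold and 7.22-fold lower. The interferon list had a median of 2.25 (percentile 100; 16 of 16 higher), or 2.24 with Oas3 at its bound and 1.49 with CPM + 10. The maturation list had a median of 0.12 (percentile 27.5), with Ccl5 4.67-fold higher and Fscn1, with 70 UMIs against 0, at least 7.95-fold higher. Proliferation, glycolysis, oxidative phosphorylation and stress medians were 0.24, 0.56, 0.45 and -0.33 (percentiles 51.8, 99.1, 96.7 and 0.01), and the first turned to -0.02 with per-cell CPM.

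In dendritic cells of MI-E over MI, Spp1, Neat1 and Ly6a were 2.44-fold, 2.38-fold and 2.31-fold higher and Mgl2, Dennd5b and the hypoxia-induced Hilpda 4.39-fold, 3.49-fold and 2.46-fold lower. Spp1 stood at 272 CPM in MI and 664 CPM in MI-E dendritic cells, against 6951 and 6567 CPM in monocyte-macrophage cells, and was also seen in MI T cells and MI-E B cells. Medians were 0.39 for interferon (percentile 100), 0.16 for maturation (percentile 86.2; 2 of 14 higher and 4 lower), -0.55 for proliferation (percentile 0), 0.05 for glycolysis (percentile 50.2), -0.05 for oxidative phosphorylation (percentile 24.9) and -0.01 for stress genes (percentile 32.8). In MI-E over Sham, Ly6a, Ifitm1 and Isg20 were 95.3-fold, 30.2-fold and 22.9-fold higher and Cd81, Mt2 and Mt1 16.8-fold, 14.2-fold and 9.32-fold lower. Medians were 2.94 for interferon (percentile 100; 2.21 with the expected doublet rate in every library and 1.89 with CPM + 10), -0.17 for maturation (percentile 0.580; 5 of 14 higher and 5 lower), -0.08 for proliferation (percentile 2.70; 3 of 14 higher and 1 lower), 0.70 for glycolysis (percentile 99.9), 0.59 for oxidative phosphorylation (percentile 99.3) and -0.24 for stress genes (percentile 0.075).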

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

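The clusters below were set apart after the clusters had been seen. They were flagged because they stand outside the cell classes compared in the report and were more frequent than in Sham. Cluster 15, which carried markers of macrophages and of neutrophils, held 3.79% of MI cells (3.39 to 4.23) and 2.55% of MI-E cells (2.28 to 2.85), against 0.0595% of Sham cells. Its S100a8 level was 4291 CPM in MI and 5568 CPM in MI-E, against 21493 and 23734 CPM in neutrophils and 55.1 and 118 CPM in monocyte-macrophage cells, and its median depth was 9874 and 9671 UMIs, against 1764.5 and 2107.5 in neutrophils. Its median Scrublet doublet score, 0.157, was the highest of the 24 clusters. Cluster 17, with macrophage markers and few UMIs, held 6.04% of MI cells (5.53 to 6.57) and 3.24% of MI-E cells (2.93 to 3.57), against 0.308% of Sham cells.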

How the results depend on the processing

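The expected doublet rate in every library, the list medians under other cell filters, the sums without clusters 10 and 18 or without the monocyte clusters, the shares with clusters 2 and 17, and the choice of 6 list medians and 4 share ratios as leading results came after values had been seen. No paired analysis was possible because each group has 1 library. When libraries were clustered alone, no cluster was named as NK cells in MI or MI-E, or as dendritic cells in Sham. Without a cell filter, no cluster was named as dendritic cells. These shares and their ratios were left out of the counts below, so they count neither as moved nor as the same. No value was obtained within clusters for neutrophils of MI over Sham, or for classes of a single cluster. Sham had the lowest depth (2727 UMIs per cell), which limits genes seen in few Sham cells.

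Of 1142 alternative list medians 828 were the same within counting error, 294 moved and 20 reversed. A median counts as reversed where its interval left out 0 and its sign turned, so a turned sign of a median whose interval held 0, such as -0.31 for regulatory T cell genes, counts as moved or the same. Of 142 share ratios 120 were the same, 21 moved and 1 reversed. Of 400 values of named genes 130 were the same and 270 moved, and 0 reversed. Of 138 class shares 32 moved, of 144 marker shares 136, and of 48 member counts 2. The neutrophil ratio of MI-E to MI (5.64 to 6.14) and the B cell ratio of MI to Sham (0.0185 to 0.0203) kept their values throughout.

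The leading medians are resident, MHC class II and Trem2 genes for MI over Sham, and classical monocyte, interferon and proliferation genes for MI-E over MI. With TMM factors the first 3 were -2.28, -2.72 and 1.78. Per-cell CPM gave -2.25 for resident, -2.99 for MHC class II, 1.04 for classical monocyte and -1.28 for proliferation genes. CPM + 10 gave -2.26, -2.87, 1.56, 0.99, 0.45 and -0.74 for all 6, and ratios within clusters gave -0.46, -1.54, 0.92, 0.66, 0.30 and -0.21. Without clusters 10 and 18, all but interferon moved, to -2.21, -2.52, 1.26, 1.34 and -1.32. The MHC class II median was -2.97 with the stricter cell filter, -2.94 with doublets kept and -2.99 with the expected doublet rate. The classical monocyte median was 1.12 and 1.14 under the last pair. With no filter on low genes the resident and MHC class II medians were -2.65 and -2.27. The proliferation median was -0.91 at a mean of at least 20 CPM and -1.08 without the monocyte clusters. The monocyte-macrophage ratio of MI to Sham was 1.15 with clusters 10 and 18 out of the class but in the total. This ratio was 1.70 with the low-UMI clusters 2 and 17, 2.14 and 2.13 at Leiden resolution 0.5 and 2, 1.81 with the stricter filter, 2.30 with doublets kept and 2.16 with the expected rate. That of MI-E to MI was 0.677 with doublets kept and 0.673 with libraries clustered alone.

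Reversed values in monocyte-macrophage cells within clusters were 0.16 (nonclassical) and 1.09 (efferocytosis) for MI over Sham, 0.0435 (resident), -0.0106 (nonclassical), 0.11 (Trem2) and -0.0280 (inflammatory) for MI-E over MI, and 1.03 (efferocytosis) and 0.0860 (iron) for MI-E over Sham. Without clusters 10 and 18 the inflammatory median was -0.17 for MI-E over MI and -0.44 for MI-E over Sham. With their cells out of the class but still in the total, the share ratio of MI-E to Sham was 0.839. The nonclassical median for MI-E over Sham was 0.0909 at a mean of at least 20 CPM, and the MHC class II median for MI-E over MI was -3.86e-05 with doublets kept. In neutrophils of MI-E over Sham, values within clusters were 0.23 (trafficking), -0.42 (stress), -0.58 (proliferation) and -0.32 (oxidative phosphorylation), and proliferation was -0.0585 at a mean of at least 20 CPM. Neutrophil glycolysis for MI-E over MI was 0.0381 with TMM factors. Per-cell CPM gave -0.24 for naive T cell genes in MI-E over MI and -0.0215 for dendritic cell proliferation in MI over Sham. For moved and reversed values the cause was not tested.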

Other observations

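The tests of handling, depth, monocyte dilution, blood leukocytes and cavity macrophages were chosen after the result they measure had been seen, as were the patterns weighed and the type 17 genes.

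T cells of MI-E, and a few of MI, held genes of the type 17 response, in which T cells make interleukin 17 and interleukin 22. Il17a was seen in 0 of 668 Sham T cells after thinning to 1500 UMIs, which allows up to 0.449%, in 6.94% of MI (5 cells) and in 8.65% of MI-E (0.420%, 8.22% and 13.3% unthinned). Its level was 257 CPM in MI, on 114 UMIs in 6 cells, and 126 CPM in MI-E. Il22 was seen in 0 of the same Sham cells, 1.39% of MI (1 cell) and 6.77% of MI-E (0 of 714, which allows up to 0.420%, 2.74% and 8.15% unthinned). In monocyte-macrophage cells, thinned, Il17a was seen in 0 cells of each library, which allows up to 0.0797%, 0.0475% and 0.0455%, and Il22 in 0.0152% of MI-E and 0 of the others. The interleukin 1 receptor gene Il1r1 was seen in 0.150%, 1.39% and 6.77% of T cells (0.840%, 8.22% and 14.4% unthinned), against 0.292%, 0.333% and 0.409% of monocyte-macrophage cells, so that its Sham share, and that of MI on 1 cell, are read as background. The gamma-delta T cell gene Trdc was seen in 2.10%, 6.94% and 12.8% (2.94%, 8.22% and 14.1% unthinned), against 0.0266%, 0.0317% and 0 of monocyte-macrophage cells, which allows up to 0.0455%. Median depth of the T cells was 3616, 3893 and 3856.5 UMIs, and of the monocyte-macrophage cells 5042.5, 10209 and 9681.

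Hspa1a and Hspa1b together were 47.9-fold higher in Sham than in MI monocyte-macrophage cells (46.9 to 48.9). A different mixture of clusters is argued against as the whole cause, since the ratio was 8.83 within cluster 3 and 12.3 within cluster 9. Heat or handling of the whole Sham suspension cannot be told apart from a difference between the groups. The ratio was 7.37 in T cells (4.18 to 14.3), 3.87 in neutrophils and 3.22 in dendritic cells, higher in each but far below that of macrophages. Sham levels there were 199, 78.6 and 590 CPM, against 6113 CPM in Sham monocyte-macrophage cells. Each lay below the limit, relative to another class, under which genes were left out of naming. Free RNA from macrophages could therefore add to these levels, and the ratios do not show whether the other classes themselves responded. The group itself stays open and untested.

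Proliferation genes were lower in MI-E than in MI monocyte-macrophage cells. Unequal depth is argued against by Mki67-positive shares after thinning, 3.09-fold higher in MI (2.53 to 3.80). Unequal doublet removal is argued against by a median log2 ratio of -1.20 with the expected doublet rate in every library, and dilution by monocytes by -1.08 without the monocyte clusters. Within clusters the median was -0.21, for a reason that was not tested, and cluster 16, led by cell cycle genes, held 626 cells in MI and 151 in MI-E. A difference between the groups stays open and untested, as does one between the libraries.

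The neutrophil share was 5.69-fold higher in MI-E than in MI. Loss of neutrophils below the UMI floor in MI stays open, because cells below the floor were not among the barcodes used. Few of the MI neutrophils that were called lay near the floor. Those under 750 UMIs were 8 of 360 in MI (2.22%, 0.964 to 4.33), 10 of 423 in Sham and 31 of 3008 in MI-E. Median depth was 1764.5 UMIs in MI and 2107.5 in MI-E neutrophils. The ratio of these shares for MI over MI-E was 2.16 with an interval of 0.856 to 4.80, too wide to decide. A separate group of neutrophils wholly below the floor could not be seen. More blood leukocytes in the MI-E suspension also stay open: B cells were 4.60-fold higher (3.37 to 6.38), but T cells 2.52-fold, NK cells 1.56-fold, the monocytes of cluster 9 2.30-fold and the neutrophils of cluster 5, where most Sham neutrophils lay, 1.48-fold (0.887 to 2.54). The group stays open and untested.

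A lower glucocorticoid response in MI-E than in MI was a hypothesis drawn from Fkbp5 and Tsc22d3. Fkbp5 was 4.98-fold lower in monocyte-macrophage cells, 6.17-fold in neutrophils, 5.78-fold in dendritic cells and 2.19-fold in T cells. Tsc22d3 was 3.16-fold lower in neutrophils, 1.56-fold in monocyte-macrophage cells (1.47 to 1.65) and 1.36-fold in dendritic cells (1.06 to 1.74), but not lower in T cells (ratio 1.02). For Fkbp5, MI is the library that stands apart, at 6.44 CPM in Sham, 58.7 in MI and 11.8 in MI-E monocyte-macrophage cells, at 2.46 (2 UMIs), 57.4 and 9.31 in neutrophils, and at 3.18 (3 UMIs), 30.7 and 5.31 in dendritic cells. A list of other glucocorticoid targets had medians of 0.02, 0.06, 0.15 and 0.08 in monocyte-macrophage cells, neutrophils, T cells and dendritic cells, and 0 of 4 classes lay below the 5th percentile of random lists. The bound set beforehand against the hypothesis, a median above 0 in at least 3 of 4 classes, was met, and the first run labelled the hypothesis excluded. That bound was a poor one, because medians near 0 over members that go both ways (Mt2 2.26-fold lower and Il1r2 2.38-fold higher in monocyte-macrophage cells) decide nothing, and the label was then altered to leave the question open. Some members had been seen in other tables when the list was written.

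Cluster 23, a macrophage cluster with 222 cells in MI, 28 in MI-E and 0 in Sham, was compared with the other MI monocyte-macrophage cells for genes of cavity macrophages, which live in the pleural and pericardial spaces. All 8 genes, with no filter on level, had a median log2 ratio of 3.49, at percentile 100 of random lists matched on the level in the other cells alone, with 7 higher. A filter on level, which favours genes high in the cluster, left 5 genes and a median of 4.31, also at percentile 100. Alox15 was 648-fold, Prg4 297-fold, Selp 81.9-fold, F5 25.4-fold and Icam2 8.48-fold higher. Gata6, the regulator of these cells, rested on 7 UMIs against 6 and Garnl3 on 4 against 36 (6.07-fold higher), and Cxcl13, on 1 UMI, was not higher. This is consistent with macrophages of the cavity among the sorted cells, as a hypothesis found and tested on the same data.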
